A study of Homo sapiens with 6 samples.

How the data were processed

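RNA was measured in 6 libraries of HEK293T cells, 3 labelled vector control and 3 labelled PRMT1 overexpression, after polyA selection, fragmentation and random priming per the labels' protocols. The deposited table gives TPM (transcript levels scaled to the same total) per Ensembl gene and library. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 with the genome build GRCh38, without their role or order. The gene annotation, the strand setting and how the authors computed the TPM values are not given in the sources used here. Each column of the table adds up to 1000000, so a gene that takes a large share lowers the TPM of all others. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes that resemble another gene are uncertain.

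All columns of the table matched the title of 1 sample each, and groups and replicate numbers were taken from the labels. Of 57500 gene identifiers, 56410 were found in a table of gene names and 40907 had a symbol there. Coordinates, gene types, exonic lengths and transcript sequences came from GENCODE 29 on GRCh38, which held 56898 of the identifiers and may differ from the annotation used for the table. TPM itself keeps no depth. Multiplied by the exonic length of each gene in GENCODE 29, however, the low values fell on whole multiples of 1 step per library. Among values under 50 reads, 95.5 to 95.7% were whole within 0.05 of a read, where chance gives 10%. On this scale the vector control libraries 1 to 3 held 20424790, 19725579 and 18196807 reads and the PRMT1 libraries 1 to 3 held 22488789, 23163982 and 19874244 reads. For a gene of 1 kb, 3 reads correspond to 0.459 to 0.526 TPM, so differences between values near or under 1 TPM rest on a few reads. Floors of 3 reads per library cover counting error only.

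Genes with at least 1 TPM in at least 3 of the 6 libraries were tested. PRMT1 and control libraries were compared on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. Before the data were examined, 38 gene lists were written from general knowledge. They cover arginine methyltransferases, PRMT1 regulators and substrates, metabolism, stress and signalling, the cell cycle, chromatin, the ribosome and the proteasome, and markers of other cell types. The 35 lists with at least 5 tested genes entered limma's camera test with a preset inter-gene correlation of 0.01, adjusted over the lists. All 16 lists that passed lost the call when camera estimated the correlation, which in a design of 3 against 3 also takes up correlation between genes of a pathway. Ranges of a list's adjusted p over the alternatives are at the preset correlation. Medians of lists are given relative to the median of all tested genes. Beside matched draws they are plain log2 fold changes. The draws, not among the choices made beforehand, took for each member 1 of the 100 nearest genes in rank of level, GC content and transcript length, 10000 times.

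Genes are named by a rule written before the data were examined. It names PRMT1 and every other tested arginine methyltransferase. Among genes past the threshold whose values do not overlap between groups, with a mean of at least 5 TPM in the higher group, it names the 10 with the largest rise and the 10 with the largest fall. It also names up to 4 members with the smallest p, in the direction of the list, of each list that passes or holds at least 3 genes past the threshold. Genes without a symbol, readthrough genes and unnamed clone genes are counted but not named.

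The fits were tested on simulated values with the means and spreads of the 15341 tested genes, in which 200 genes were changed. In this simulation, limma recovered 21.2% of the genes changed by 0.5 on the log2 scale, 56.7% of those changed by 1 and 88.1% of those changed by 2. It called 4 of 15141 unchanged genes. Camera called a simulated list raised by 0.4 (adjusted p = 2.7e-24) and 0 of 30 unchanged lists. Genes were drawn independently, so the unchanged lists do not test camera on correlated genes. Only 200 genes were changed, against 7515 called in the data, so the recovery rates do not carry over to the data. Replicates were compared before averaging. Recovered reads of libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 2.76 to 25.5, so no library was taken for a duplicate.

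The alternatives fixed beforehand were pseudocounts of 0.1 and 5 TPM, no filter and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without PRMT1 and without the mitochondrially encoded genes, no variance trend, array weights, the replicate number as a block, each library left out in turn, a fold change of at least 2, a threshold of 0.1 and an estimated inter-gene correlation. A GC correction per library (lowess on the GC content of the longest transcript, span 0.3, for 99.6% of the tested genes), limma's voom on the recovered reads and a fit without the vector control library 3 and the PRMT1 library 2 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.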

Results

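Gene expression was measured by polyA-selected RNA sequencing in HEK293T cells, an established human embryonic kidney line that takes up plasmid DNA readily. The series holds 6 libraries in 2 groups of 3. The control libraries carry a vector control label and are titled mock. The PRMT1 libraries come from cells given, with the PolyJet reagent, a pcDNA3 plasmid that expresses PRMT1. The protocol mentions transfection for the PRMT1 condition, and the labels do not say whether the control cells received an empty plasmid. PRMT1 is the main enzyme that places asymmetric dimethyl marks on arginine residues of proteins, and the title of the series concerns how acetylation and ubiquitination set its level. The comparison asks which transcripts differ between cells with the PRMT1 plasmid and control cells. The deposited values are TPM, transcript levels scaled to a total of 1000000 per library, for 57500 Ensembl gene identifiers. Between 18196807 and 23163982 reads per library could be recovered from them, as described under processing. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

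PRMT1 (ENSG00000126457, chromosome 19, 49675786 to 49689029, plus strand, GRCh38 with GENCODE 29) was 192-fold higher in the PRMT1 libraries. Its level was 381 ± 14.7 TPM (SD, n = 3) in the controls and 73160 ± 11090 TPM (SD, n = 3) in the PRMT1 libraries. The single libraries held 378, 397 and 368 TPM in the controls and 71660, 62890 and 84920 TPM with the plasmid, so every library matched its label. The log2 fold change was 7.57 (SE 0.10, limma adjusted p = 5.5e-08). An exact two-sided permutation test of the 3 against 3 values gave p = 0.1, the smallest that 10 splits allow. PRMT1 took 0.037 to 0.04% of all TPM in the controls and 6.29 to 8.49% in the PRMT1 libraries, or 10343 to 11345 against 1944518 to 2323530 recovered reads. Values per gene do not separate transcripts of the plasmid from those of the chromosomal gene. The processed pseudogene PRMT1P1 (chromosome 5, 177265580 to 177266588, inside NSD1 and on the opposite strand) was listed at 0 in the 3 controls and at 8.04, 7.38 and 7.64 TPM in the PRMT1 libraries. That is at least 15.6-fold higher against a floor of 3 reads per library. Its sequence resembles that of PRMT1, so reads of the transfected gene can be assigned to it and its own level is uncertain.

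The difference reached across the transcriptome. Of 15341 genes tested, 6190 were higher and 1325 were lower in the PRMT1 libraries (limma, Benjamini-Hochberg adjusted p under 0.05), together 7515 genes or 49%. A change of at least 2-fold was seen for 1528 higher and 131 lower genes. The 3 values of each group did not overlap for 9415 genes, 61.4% of those tested, where chance gives 10%. The median log2 fold change of all tested genes was 0.30 in TPM, and the excess of higher genes depended on the scaling. After median-of-ratios scaling, which moved that median to 0.006, 3605 genes were higher and 3692 lower, and quantile normalization gave 3109 higher and 2979 lower. With PRMT1 taken out and the rest rescaled the split was 7601 higher and 880 lower. After GC correction 8 genes passed in the opposite direction. Below, rose and fell refer to TPM as deposited, counts after median-of-ratios scaling follow as scaled counts, and medians of gene lists are relative to the median of all genes. Members named by the rule lie in the direction of the list's camera test, so the counts, not the names, give the balance of a list.

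The TPM was spread over more genes in the PRMT1 libraries. Of the TPM outside PRMT1, the 500 most abundant other genes held 64.2 ± 1.39% (SD, n = 3) in the controls and 57.09 ± 1.88% (SD, n = 3) in the PRMT1 libraries. Between 14436 and 14526 genes reached 1 TPM in the control libraries and between 15641 and 16075 in the PRMT1 libraries. Among protein-coding genes the median log2 fold change was 0.43 in the decile with the lowest expression and -0.14 in the decile with the highest. It was 0.50 in the decile of lowest GC content and 0.01 in the decile of highest GC content. The libraries of a group also differed in this respect. The deviation of a library from its group, lowest minus highest GC decile, was 0.32 in the PRMT1 library 2. It was -0.12 and -0.20 in the PRMT1 libraries 1 and 3, and -0.09 to 0.05 in the controls. The first principal component took 69.2% of the variance and separated the groups. The vector control library 3 and the PRMT1 library 2 stood apart within their groups, and without these 2 libraries 5285 genes were higher and 2082 lower.

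Apart from PRMT1 and its pseudogene, the genes with the largest rises were a mixed set of protein-coding genes, pseudogenes and a noncoding RNA. ZNF79, a zinc finger gene (chromosome 9, 127424374 to 127445372), went from 0.70 ± 0.06 to 24.5 ± 1.57 TPM (SD, n = 3 each), a log2 fold change of 3.91 (SE 0.11, limma adjusted p = 5.67e-06). OVGP1, which encodes an oviduct glycoprotein (chromosome 1, 111414314 to 111427777), went from 0.82 ± 0.12 to 15.1 ± 1.33 TPM, and AMH, the gene of anti-Müllerian hormone (chromosome 19, 2249309 to 2252073), from 5.26 ± 0.12 to 46.0 ± 1.61 TPM. SNHG15, a spliced noncoding host gene of the small nucleolar RNA SNORA9 (chromosome 7, 44983023 to 44986961), went from 9.79 ± 1.64 to 87.2 ± 4.49 TPM. POMZP3, which shares sequence with POM121 and ZP3, went from 2.14 ± 0.23 to 22.7 ± 2.19 TPM. The log2 fold changes of these last 4 genes lay between 2.91 and 3.14 (adjusted p at most 2.73e-05). The pseudogenes ISCA1P4, ASNSP1 and SLC7A5P1 had log2 fold changes of 4.32, 3.07 and 2.99. They rest on 6, 48 and 55 recovered reads over the 3 controls and 129, 789 and 494 over the PRMT1 libraries. Their values are uncertain because they resemble ISCA1, ASNS and SLC7A5, whose own log2 fold changes were 0.34, 0.75 and 0.36.

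The genes with the largest falls were likewise a mixed set of protein-coding genes, mitochondrial tRNA genes and other noncoding genes. HSPA6, a heat-inducible HSP70 chaperone gene (chromosome 1, 161524540 to 161526910), fell from 17.6 ± 2.44 to 0.88 ± 0.47 TPM (SD, n = 3 each), a log2 fold change of -3.33 (SE 0.21, limma adjusted p = 7.27e-05). EGR1, an early growth response transcription factor (chromosome 5, 138465490 to 138469315), fell from 36.1 ± 5.86 to 3.04 ± 0.24 TPM, a log2 fold change of -3.19 (SE 0.14, adjusted p = 3.13e-05). SOCS1, a feedback inhibitor of cytokine signalling (chromosome 16, 11254405 to 11256200), fell from 15.01 ± 3.00 to 1.28 ± 0.65 TPM. The histone gene H2BC21 (chromosome 1, 149884459 to 149886652) fell from 246 ± 28.9 to 34.3 ± 4.56 TPM, a log2 fold change of -2.81 (adjusted p = 3.13e-05). The other members of this set are short or overlap another gene and rest on few reads. The mitochondrial tRNA genes MT-TL2, MT-TH and MT-TA had log2 fold changes of -4.14, -2.47 and -2.43, from 104, 48 and 19 recovered reads over the 3 controls and 10, 9 and 4 over the PRMT1 libraries. SNORD100, which lies within RPS12, and MNX1-AS2, which overlaps MNX1 on the other strand, had log2 fold changes of -2.39 and -2.38 from 11 and 46 control reads. SNORA71A, which lies within SNHG17, was listed at 7.15, 10.0 and 5.09 TPM in the controls and at 0 in the 3 PRMT1 libraries, at least 2.06-fold lower against a floor of 3 reads per library. The call of SNORD100 was lost without the 2 libraries that stand apart (adjusted p = 0.0701) and with array weights (-1.05, adjusted p = 0.0826), and that of MT-TA without the expression filter (adjusted p = 0.0529) or with a pseudocount of 0.1 TPM (-3.66, adjusted p = 0.0574).

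**Figure D1:**
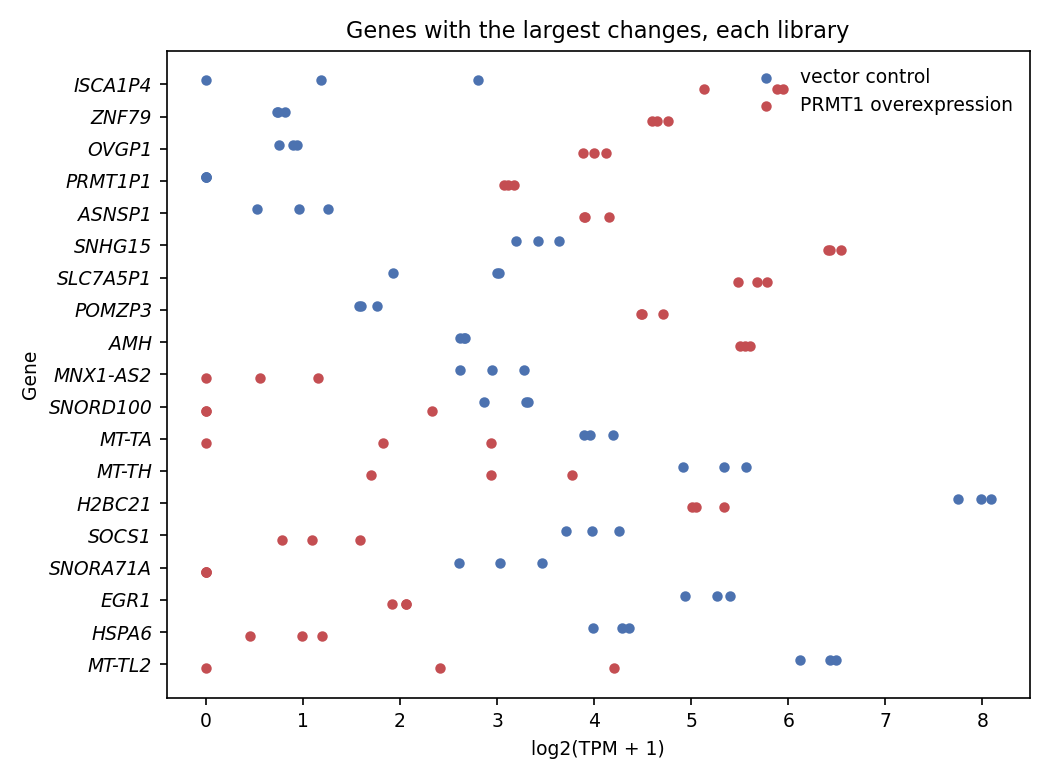
log2(TPM + 1) of each library for the 19 genes other than PRMT1 with the largest changes, from the largest rise at the top to the largest fall at the bottom, with blue points for the 3 vector control and red points for the 3 PRMT1 libraries. The points of the groups do not overlap for any of these genes, and PRMT1P1 lies at 0 in the controls.

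Several other arginine methyltransferase genes were also higher, but in TPM as deposited not PRMT2 or CARM1. Of 9 tested members of this family, PRMT1 included, 7 rose and 0 fell, the same counts adjusted over the list alone, with 5 rising and 1 falling after scaling. PRMT6, which methylates histone H3, rose from 12.5 ± 0.44 to 42.9 ± 3.54 TPM (SD, n = 3 each), a log2 fold change of 1.70 (SE 0.09, limma adjusted p = 5.35e-05). PRMT7 rose from 4.21 ± 0.09 to 14.1 ± 1.09 TPM and PRMT9 from 2.14 ± 0.15 to 6.70 ± 0.30 TPM, log2 fold changes of 1.54 and 1.30. PRMT5, the main enzyme for symmetric dimethylation, rose from 122 ± 29.8 to 228 ± 9.18 TPM (log2 fold change 0.93, adjusted p = 0.00349). PRMT3 (0.58, adjusted p = 0.0174) and the mitochondrial methyltransferase NDUFAF7 (0.40, adjusted p = 0.0274) passed in TPM but not after scaling (adjusted p = 0.108 and 0.673). NDUFAF7 also missed the threshold without vector control replicate 1 or 3 or PRMT1 replicate 1 or 2 (adjusted p = 0.0984, 0.0505, 0.103 and 0.0529). PRMT2 had a log2 fold change of 0.17 (adjusted p = 0.187), which was -0.18 after scaling. With PRMT1 taken out and the rest rescaled, PRMT2 was higher past the threshold (0.27, adjusted p = 0.0427). CARM1 had a log2 fold change of -0.10 (adjusted p = 0.328). It was -0.46 and past the threshold after scaling (adjusted p = 0.00305), and -0.18 without vector control replicate 3 (adjusted p = 0.0357). The list passed the camera test (adjusted p = 0.013), with adjusted p = 0.49 with an estimated correlation. Once PRMT1 was taken out and the rest rescaled the list missed the threshold (adjusted p = 0.052, the highest at the preset correlation, with a lowest of 0.00045).

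**Figure D2:**
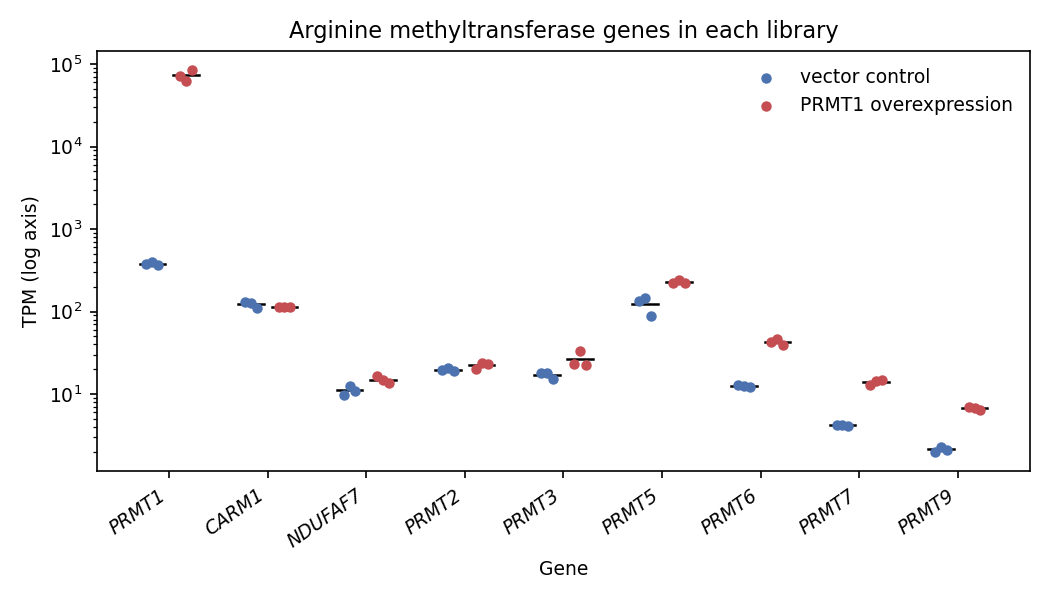
TPM, on a log axis, of the 9 tested arginine methyltransferase genes in each library. Blue points are the 3 vector control and red points the 3 PRMT1 libraries, and black lines are group means. PRMT1 stands at 381 against 73160 TPM, and PRMT6, PRMT7 and PRMT9 are higher in every PRMT1 library than in any control.

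The lists of PRMT1 regulators, of methylarginine readers and turnover genes and of the methyl donor cycle did not pass the camera test. Of 18 tested enzymes and partners that govern PRMT1 acetylation and ubiquitination, 9 rose and 0 fell, also adjusted over the list alone, with 5 rising and 5 falling after scaling (camera adjusted p = 0.54). The deubiquitinase gene USP7 rose by 0.91 on the log2 scale, and the PRMT1-binding antiproliferative genes BTG1 and BTG2 by 0.64 and 0.67, BTG1 not after GC correction (adjusted p = 0.132). The acetyltransferase gene KAT5 rose by 0.55, a call lost after scaling (adjusted p = 0.0581). Of 10 tested methylarginine readers and turnover genes, 3 rose and 1 fell, also adjusted over the list alone, with 1 and 3 after scaling (camera adjusted p = 0.67). The falling gene was DDAH2 (-0.51, adjusted p = 0.00391). DDAH1 and SND1 had values of -0.09 and -0.16 and did not pass, and SND1 passed without vector control replicate 3 (-0.22, adjusted p = 0.0145). After scaling both were lower past the threshold (-0.44 and -0.51, adjusted p = 0.00654 and 0.00231), as they were after GC correction, while DDAH1 was at 0.02 with PRMT1 taken out and the rest rescaled. Of 16 tested genes of the methionine and S-adenosylmethionine cycle, which supplies the methyl donor, 9 rose and 2 fell, also adjusted over the list alone, and 4 rose and 4 fell after scaling (camera adjusted p = 0.7). CTH, MTRR, MAT2A and MAT2B rose by 1.81, 1.13, 0.72 and 0.67 (adjusted p at most 0.00272), MAT2B not after GC correction (adjusted p = 0.091).

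RNA-binding proteins that PRMT1 methylates, a list of 30 tested genes, held 12 that rose and 3 that fell, also adjusted over the list alone, and 8 and 12 after scaling (camera adjusted p = 0.92). CHTOP, SFPQ and CIRBP rose by 1.48, 1.18 and 0.81 on the log2 scale (SE 0.07 to 0.08, limma adjusted p at most 0.000165). This list passed upward under quantile normalization alone (adjusted p = 0.00043, against up to 1 under other settings). Among 32 tested serine-arginine and core splicing factors, 11 rose and 5 fell, also adjusted over the list alone, and 8 and 16 after scaling, but 10 and 4 under quantile normalization, where the list was higher without passing (camera adjusted p = 0.42, and 0.1 under quantile normalization, with up to 0.77 at the preset correlation). SNRPD2, SRSF4, SNRNP70 and SF3B2 fell by 0.40, 0.36, 0.31 and 0.31 (adjusted p at most 0.0159), and the calls of SNRPD2 and SNRNP70 were lost under quantile normalization (adjusted p = 0.185 and 0.329). The serine-arginine factor genes SRSF6 and SRSF3, chosen after their values were seen, rose by 1.23 and 0.98 (adjusted p at most 0.000398).

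Genes of glycolysis, respiration and the cytosolic ribosome were lower than other genes. Of 34 tested glycolysis and hypoxia genes, 14 fell and 1 rose, with 13 and 1 adjusted over the list alone and 30 and 1 after scaling, and the median lay 0.56 (log2) below that of all genes, or 0.30 below it under quantile normalization. GAPDH, a central glycolytic enzyme, fell from 11940 ± 634 to 6405 ± 132 TPM (SD, n = 3 each), and ALDOA, ALDOC and GPI fell by 0.74, 0.94 and 0.69 on the log2 scale (limma adjusted p at most 0.000195). The camera test gave adjusted p = 7.2e-12 for this list and adjusted p = 0.44 with an estimated correlation. Of 62 nuclear-encoded oxidative phosphorylation genes, 29 fell and 0 rose, also adjusted over the list alone, and 58 and 0 after scaling, but 13 fell and 1 rose under quantile normalization. The median lay 0.53 below that of all genes, and 0.14 below it under quantile normalization. The complex III subunit gene CYC1, the ATP synthase gene ATP5MC1 and the complex I genes NDUFB10 and NDUFS7 fell by 0.46, 0.54, 0.58 and 0.55 (SE 0.06 to 0.08). The camera adjusted p was 1.8e-19, with adjusted p = 0.24 under an estimated correlation. Of 79 cytosolic ribosomal protein genes, 44 fell and 0 rose, 48 and 0 adjusted over the list alone and 78 and 0 after scaling, but 1 fell and 6 rose under quantile normalization. Their sum was 18.24 ± 0.50% of the TPM outside PRMT1 (SD, n = 3) in the controls and 16.71 ± 0.59% (SD, n = 3) in the PRMT1 libraries. RPL10, RPL7A, RPS2 and RPS3 fell by 0.36, 0.47, 0.28 and 0.33 (adjusted p at most 0.00179). The list median lay 0.53 below that of all genes (camera adjusted p = 1.4e-26, and adjusted p = 0.24 with an estimated correlation). It lay 0.04 above it under quantile normalization (adjusted p = 0.39, the highest at the preset correlation, with a lowest of 2.8e-27), where the calls of RPL10, RPL7A and RPS3 were lost too. The call of RPS2 was lost without the expression filter (adjusted p = 0.105). With PRMT1 taken out and the rest rescaled, fewer genes of these lists fell. In glycolysis 12 fell and 2 rose, in oxidative phosphorylation 14 and 2, and in the ribosomal list 20 and 0. The list medians then still lay 0.541, 0.515 and 0.519 below that of all genes.

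Among the 13 mitochondrially encoded messengers, 3 rose and 2 fell, also adjusted over the list alone, and 1 rose and 3 fell after scaling, but 6 rose and 3 fell under quantile normalization and 7 rose and 2 fell without the 2 libraries that stand apart, where the median was above that of all genes (camera adjusted p = 0.058, with 0.0096 to 0.97 at the preset correlation). MT-ND1, a complex I subunit gene, fell from 8579 ± 1346 to 2932 ± 534 TPM (SD, n = 3 each), and MT-ND2 from 5321 ± 809 to 1923 ± 248 TPM, log2 fold changes of -1.55 and -1.46 (SE 0.15 and 0.13, limma adjusted p at most 0.000297). MT-CO1 had a log2 fold change of -0.27 (adjusted p = 0.117), and passed without PRMT1 replicate 1 (-0.38, adjusted p = 0.0461) and after scaling (-0.63, adjusted p = 0.0352). Its value under quantile normalization (-1.24, adjusted p = 6.19e-06) is not by itself evidence of a fall. That setting assigns values by rank, and PRMT1 ranked below MT-CO1 in every control but above it in every PRMT1 library. MT-ND3 had a log2 fold change of -0.22 (adjusted p = 0.286), which was 0.07 under quantile normalization. Of the 19 tested mitochondrial tRNA genes, 10 fell and 0 rose.

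**Figure D3:**
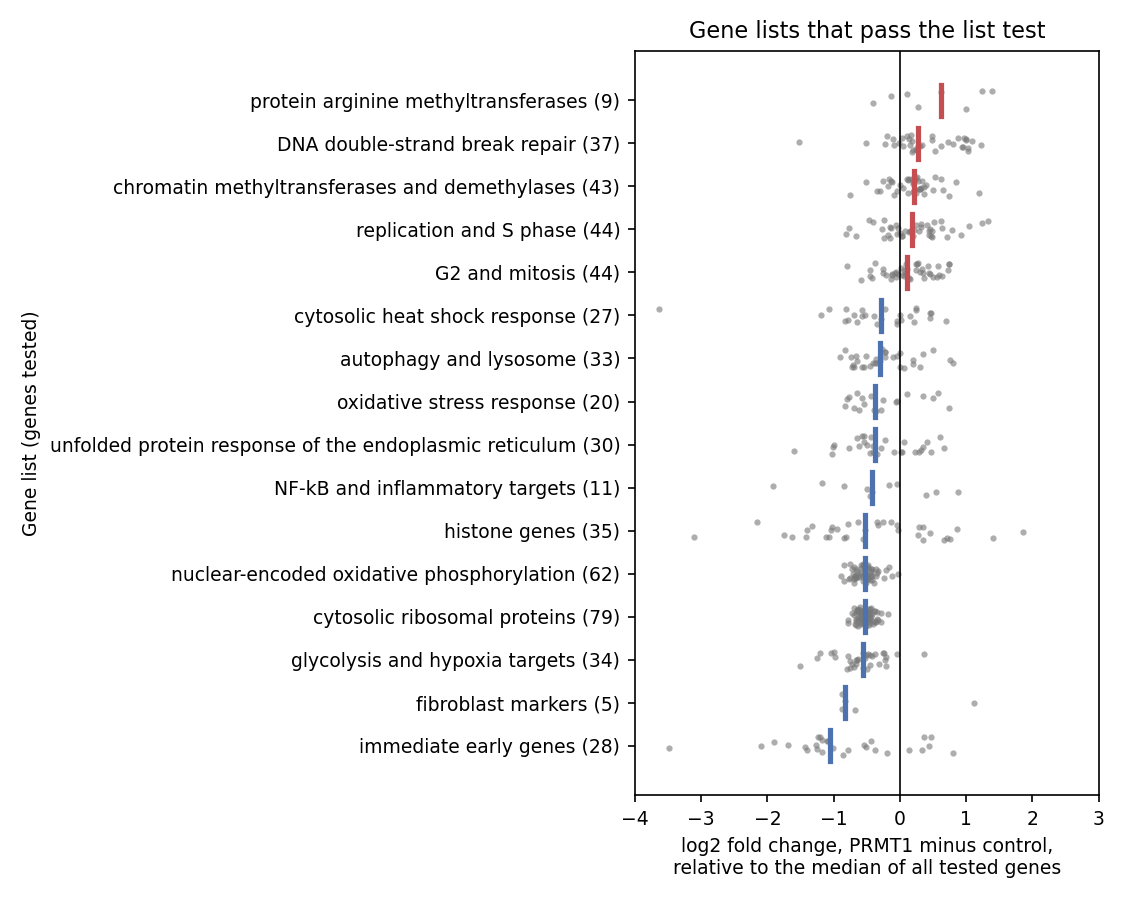
Log2 fold change (PRMT1 minus control libraries) of each tested member, as grey points, of the 16 gene lists that pass the camera test, relative to the median of all tested genes at 0. Coloured bars are list medians, red for lists tested as higher and blue for lists tested as lower, and PRMT1 itself lies off the axis. Immediate early genes have the lowest median, 1.05 below that of all genes, while the medians of the heat shock and ribosomal protein lists lie above 0 under quantile normalization.

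Immediate early genes, which respond within minutes to growth signals and stress, held the lowest median of the lists, 1.05 (log2) below that of all genes. Of 28 tested, 18 fell and 6 rose, also adjusted over the list alone, and 20 and 4 after scaling. Besides EGR1, FOS fell from 84.7 ± 0.20 to 23.8 ± 1.36 TPM (SD, n = 3 each), CCN1 from 86.0 ± 5.75 to 27.7 ± 1.56 TPM and JUNB from 213 ± 12.5 to 96.6 ± 2.58 TPM, log2 fold changes of -1.79, -1.60 and -1.13 (limma adjusted p at most 6.99e-05). The 6 rising members included MYC and BTG2 (0.74 and 0.67). The camera adjusted p was 1e-10, with adjusted p = 0.17 under an estimated correlation. Of 11 tested NF-kB and inflammatory targets, 3 rose and 3 fell, also adjusted over the list alone, and 2 and 6 after scaling. The inhibitor gene NFKBIA fell from 45.6 ± 4.24 to 14.2 ± 0.85 TPM, and TNFAIP3 and IER3 fell by 0.87 and 0.55 on the log2 scale. SOD2 had a value of -0.20 (adjusted p = 0.197), and passed after scaling (-0.54, adjusted p = 0.00141). This list passed narrowly (camera adjusted p = 0.044, adjusted p = 0.44 with an estimated correlation). It missed the threshold without vector control replicate 1 (0.055), without PRMT1 replicate 2 (0.092) and after scaling (0.19), in a range of 0.03 to 0.43 at the preset correlation.

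Histone genes went both ways, with 13 of 35 falling and 8 rising, also adjusted over the list alone, and 14 and 7 after scaling. H1-2, H1-10 and H2BC12 fell by 1.45, 0.74 and 0.72 on the log2 scale (limma adjusted p at most 0.000256). The polyA selection limits these values mostly to histone transcripts with a polyA tail, so they do not give the level of all histone messengers. The list median lay 0.52 below that of all genes (camera adjusted p = 0.00012, and adjusted p = 0.44 with an estimated correlation), and the call was lost after GC correction (adjusted p = 0.089, the highest at the preset correlation, with a lowest of 1.7e-06). Of 30 tested genes of the unfolded protein response, 8 fell and 10 rose, 9 and 10 adjusted over the list alone and 18 and 6 after scaling. The chaperone gene HSPA5 fell from 9077 ± 515 to 3715 ± 332 TPM (SD, n = 3 each), HSP90B1 from 1015 ± 31.2 to 627 ± 93.8 TPM, and CALR and DERL3 by 0.47 and 0.70, while the sensor gene ATF6 and the transcription factor gene XBP1 rose by 0.77 and 0.91. ATF6 and XBP1 were singled out after their values were seen. The camera adjusted p was 0.012, with adjusted p = 0.86 under an estimated correlation. It was 0.32 under quantile normalization, the highest at the preset correlation, with a lowest of 0.0077.

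Of 27 tested cytosolic heat shock genes, 9 fell and 9 rose, 9 and 10 adjusted over the list alone and 13 and 4 after scaling, but 5 fell and 8 rose under quantile normalization. Besides HSPA6, the cochaperone gene DNAJB1 fell from 295 ± 6.03 to 158 ± 5.08 TPM (SD, n = 3 each), and HSP90AB1 fell by 0.40 on the log2 scale (limma adjusted p at most 0.00214), HSP90AB1 not under quantile normalization. The list was lower by the camera test (adjusted p = 0.017, and adjusted p = 0.86 with an estimated correlation). It was higher without passing under quantile normalization (adjusted p = 0.56, the highest at the preset correlation, with a lowest of 0.011), and missed the threshold without the 2 libraries that stand apart (0.08). Its median, 0.01, lay at percentile 21.02 of draws of genes matched on level, GC content and transcript length, which had 0.09. Of 20 tested oxidative stress genes, 8 fell and 4 rose, 8 and 5 adjusted over the list alone and 11 and 4 after scaling (camera adjusted p = 0.0039, with adjusted p = 0.49 under an estimated correlation). It missed the threshold under quantile normalization (0.27, the highest at the preset correlation, with a lowest of 0.0037). Its median, -0.07, lay at percentile 3.32 of the matched draws (0.11). The ferritin genes FTL and FTH1 fell by 0.53 and 0.39, FTH1 not under quantile normalization (adjusted p = 0.0988), and the transketolase gene TKT by 0.46. Of 33 tested autophagy and lysosome genes, 9 fell and 9 rose, also adjusted over the list alone, and 19 and 4 after scaling (camera adjusted p = 0.011, and adjusted p = 0.86 with an estimated correlation). The lysosomal enzyme genes CTSD, GAA, NEU1 and CTSB fell by 0.61, 0.53, 0.38 and 0.35.

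Lists of cell cycle and DNA repair genes were higher than other genes. Of 37 tested double-strand break repair genes, 27 rose and 1 fell, 28 and 1 adjusted over the list alone and 17 and 3 after scaling, with a median 0.28 (log2) above that of all genes. EME1, an endonuclease subunit gene, rose from 6.65 ± 0.26 to 19.1 ± 2.38 TPM (SD, n = 3 each), a log2 fold change of 1.39, and XRCC3 and BLM rose by 1.30 and 1.52 on the log2 scale (limma adjusted p at most 0.000266). The camera adjusted p was 0.0039, with adjusted p = 0.86 under an estimated correlation. The list median was 0.58 against 0.42 in draws of matched genes (percentile 96.01), so much of this rise is shared by genes of the same level, GC content and transcript length. Of 44 tested replication and S phase genes, 28 rose and 3 fell, 29 and 3 adjusted over the list alone and 17 and 7 after scaling. The chromatin assembly gene CHAF1A rose from 31.0 ± 2.75 to 91.8 ± 0.72 TPM, and DTL, CDC6 and TK1 rose by 1.64, 1.23 and 0.79. The list median was 0.18 above that of all genes (camera adjusted p = 0.011, and adjusted p = 0.86 with an estimated correlation), and the call was lost after scaling (adjusted p = 0.14, the highest at the preset correlation, with a lowest of 4.4e-06). Of 44 tested G2 and mitosis genes, 27 rose and 1 fell, 28 and 1 adjusted over the list alone and 13 and 7 after scaling. PRC1, CDC25C, CDCA8 and CCNB1 rose by 1.02, 0.89, 0.86 and 0.64. This list passed narrowly (camera adjusted p = 0.044, and adjusted p = 0.86 with an estimated correlation). Its adjusted p was 0.066 without vector control replicate 1 or 2, 0.49 after scaling and 0.6 after GC correction, the highest at the preset correlation, with a lowest of 3.5e-05. Against matched draws, the replication list had a median log2 fold change of 0.49 against 0.11 (percentile 100). The G2 and mitosis list had 0.40 against 0.17 (percentile 99.79).

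Of 43 tested chromatin methyltransferases and demethylases, 31 rose and 1 fell, also adjusted over the list alone, and 13 and 5 after scaling. The H3K27 methyltransferase gene EZH2 rose from 25.3 ± 1.00 to 46.1 ± 3.69 TPM (SD, n = 3 each), and NSD1, SETD2 and SETD1A rose by 1.15, 1.05 and 0.69 on the log2 scale (limma adjusted p at most 0.00104). The camera adjusted p was 0.013, with adjusted p = 0.86 under an estimated correlation. It was 0.063 after scaling and under quantile normalization, the highest at the preset correlation, with a lowest of 2.4e-05. Of 35 tested ribosome biogenesis and MYC target genes, 23 rose and 4 fell, also adjusted over the list alone, and 11 and 10 after scaling (camera adjusted p = 0.24). The nucleolar genes NOP58, WDR43, NOP2 and NOP56 rose by 1.95, 1.62, 1.52 and 0.87 (adjusted p at most 0.000122). The list passed under quantile normalization (adjusted p = 0.00011), in a range reaching 0.67 at the preset correlation. Of 30 tested p53 targets, 17 rose and 3 fell, 19 and 3 adjusted over the list alone and 11 and 5 after scaling (camera adjusted p = 0.35). The list passed without the expression filter (adjusted p = 0.041), in a range reaching 0.44 at the preset correlation. AEN, an apoptosis-enhancing nuclease gene, rose from 15.5 ± 1.09 to 66.1 ± 0.67 TPM, and DDB2, TIGAR and GDF15 rose by 1.41, 1.41 and 1.03. The chromatin, ribosome biogenesis and p53 lists lay at percentiles 99.69, 100 and 99.12 of matched draws. Their median log2 fold changes were 0.52, 0.49 and 0.53, against 0.30, 0.07 and 0.27 in the draws.

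Of 34 tested amino acid response genes and ATF4 targets, 19 rose and 6 fell, 20 and 7 adjusted over the list alone and 11 and 10 after scaling (camera adjusted p = 0.61). Besides CTH and GDF15, the amino acid transporter gene SLC3A2 and the pseudokinase gene TRIB3 rose by 0.78 and 1.04 on the log2 scale. Among 38 proteasome subunit genes, 15 rose and 3 fell, also adjusted over the list alone, and 6 and 15 after scaling (camera adjusted p = 0.84). PSMD7, PSMD14, PSMC2 and PSMC4 rose by 0.89, 0.82, 0.72 and 0.64, the last not after scaling (adjusted p = 0.0834). Both lists passed upward under quantile normalization (adjusted p = 0.035 and 0.00092), in ranges reaching 0.92 and 0.96 at the preset correlation. Among 26 tested sterol synthesis genes, 10 rose and 0 fell, 9 and 0 adjusted over the list alone and 6 and 9 after scaling (camera adjusted p = 0.92). HSD17B7, MVK, NSDHL and PMVK rose by 0.92, 0.66, 0.66 and 0.61, MVK not under quantile normalization. The amino acid, proteasome and sterol lists lay at percentiles 99.95, 89.02 and 84.8 of matched draws. Their median log2 fold changes were 0.42, 0.15 and 0.28, against 0.11, 0.07 and 0.18 in the draws.

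Type I interferon genes held 8 of 15 tested that rose and 1 that fell, also adjusted over the list alone, and 3 and 3 after scaling (camera adjusted p = 0.64). IFIT5, IFIT1, RIGI and ISG15 rose by 1.34, 0.92, 0.86 and 0.60 on the log2 scale from levels of 0.55 to 7.73 TPM, ISG15 not after scaling (adjusted p = 0.152) and RIGI not under quantile normalization (adjusted p = 0.0574). Of 15 tested cytosolic DNA and RNA sensing genes, 6 rose and 0 fell, also adjusted over the list alone, and 4 and 3 after scaling (camera adjusted p = 0.82). TBK1, IRF3 and ZC3HAV1 rose by 0.97, 0.72 and 0.69, ZC3HAV1 not under quantile normalization (adjusted p = 0.0795). The TGF-beta and BMP targets held 9 that rose and 6 that fell of 21 tested, 10 and 6 adjusted over the list alone and 1 and 8 after scaling (camera adjusted p = 0.24). TGFB1 fell from 141 ± 3.70 to 88.1 ± 5.31 TPM (SD, n = 3 each), and CCN2 and COL1A1 fell by 0.96 and 0.57. Of 17 tested WNT targets, 9 rose and 0 fell, also adjusted over the list alone, and 4 and 2 after scaling (camera adjusted p = 0.52). MYC, RNF43, WNT11 and CCND1 rose by 0.74, 0.70, 0.59 and 0.59, WNT11 not after scaling (adjusted p = 0.0876) and RNF43 not under quantile normalization. The epithelial and mesenchymal list had 6 of 20 tested that rose and 5 that fell, also adjusted over the list alone, and 4 and 10 after scaling. SNAI1, a repressor of epithelial genes, fell from 13.7 ± 2.68 to 3.49 ± 0.58 TPM, and SPARC, MMP2 and VIM fell by 0.62, 0.52 and 0.49. The list did not pass (camera adjusted p = 0.05, with 0.027 to 0.21 at the preset correlation).

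Among the marker lists, most tested fibroblast markers fell, and the kidney, neuronal and squamous markers went both ways. Of 5 tested fibroblast markers, 4 fell and 1 rose, also adjusted over the list alone and after scaling. COL1A1, COL5A1, MMP2 and FBLN1 fell by 0.57, 0.57, 0.52 and 0.37 on the log2 scale, and the rising gene was ACTA2 (1.41), named after its value was seen. The list passed the camera test (adjusted p = 0.011, and adjusted p = 0.49 with an estimated correlation) but not after scaling (0.067) or GC correction (0.087, the highest at the preset correlation, with a lowest of 0.0051). Of 11 tested neuronal and neuroendocrine markers, 5 rose and 3 fell, also adjusted over the list alone, and 1 and 4 after scaling (camera adjusted p = 0.35). NEFM, STMN2 and NEFL fell by 0.77, 0.47 and 0.41, and NCAM1 had a value of -0.01. NCAM1 was lower past the threshold after scaling (-0.35, adjusted p = 0.0497) and under quantile normalization (-0.40, adjusted p = 0.0315), and at 0.09 with PRMT1 taken out. It ranged from -0.20 without vector control replicate 3 to 0.09 without replicate 2. STMN2 missed the threshold without vector control replicate 2 (adjusted p = 0.0506) or PRMT1 replicate 1 (0.0507). Of 8 tested kidney epithelium markers, 3 rose and 1 fell, also adjusted over the list alone, and 2 and 2 after scaling (camera adjusted p = 0.8). SIX2 fell by 0.28, not without PRMT1 replicate 1 (adjusted p = 0.0745), and PAX2 had a value of -0.10 (adjusted p = 0.56), but was lower past the threshold after scaling (-0.38, adjusted p = 0.0367) and under quantile normalization (-0.55, adjusted p = 0.00978). Of 8 tested squamous and cervical line markers, 2 rose and 1 fell, 2 and 0 adjusted over the list alone and 2 and 1 after scaling (camera adjusted p = 0.86). KRT17, at 1.57 ± 0.42 TPM in the controls, fell by 0.67, not without PRMT1 replicate 1 (adjusted p = 0.0877) or 2 (0.121), and SFN had a value of -0.10. Too few leukocyte (2), endothelial (2) and hepatocyte (0) markers reached the filter for a list test. Of these, the endothelial marker EGFL7 fell by 0.64 and the others did not pass, while 1 rose and 1 fell among the endothelial markers adjusted over the list alone.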

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

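The GC correction, voom on recovered reads and the fit without the 2 libraries that stand apart were chosen after the results were seen. PRMT1 stayed higher and past the threshold under the 19 alternatives that keep it. Of the other comparisons of named genes with an alternative, 2843 kept direction and side of the threshold, 51 lost the call, 40 gained it and 18 changed direction. For the 16 gene lists that passed, 284 kept both, 49 lost the call and 2 changed direction. Of the others, the RNA-binding, sterol and proteasome lists were higher in TPM but lower after median-of-ratios scaling, without passing in either, and the WNT list was lower under quantile normalization, without passing. The list of cytosolic DNA and RNA sensing turned lower under quantile normalization and voom, and the squamous list turned higher after median-of-ratios scaling and voom, also without passing. Values below are log2 fold changes, and the cause was not tested except where the scaling itself moves the median of all genes.

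Median-of-ratios scaling gave 3605 higher and 3692 lower genes and PRMT2 at -0.177. Quantile normalization gave 3109 and 2979, PRMT2 at -0.162, NDUFAF7 at 0, MT-ND3 at 0.075, and medians relative to all genes of 0.105 for the heat shock list and 0.041 for the ribosomal protein list. With PRMT1 taken out and the rest rescaled, 880 genes were lower, with CARM1 at 0.006, DDAH1 at 0.016 and NCAM1 at 0.089. Array weights gave 2838 lower genes and MT-ND3 at 0.041. The GC correction gave 3613 higher and 3878 lower genes, PRMT2 at -0.176 and NDUFAF7 at -0.061. Voom gave 3957 and 3948 with PRMT2 at -0.186. Without the 2 libraries that stand apart 2082 genes were lower, MT-ND3 was at 0.061 and SFN at 0.336. With 1 library left out at a time, NCAM1 ranged from -0.201 to 0.088 and SFN from -0.463 to 0.168. A fold change of at least 2 left 1659 genes past the threshold, 1528 higher and 131 lower. With an estimated inter-gene correlation 0 lists passed.

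Taking the replicate number as a block gave 7589 genes past the threshold. The numbers did not pair the samples, since the deviations of libraries with the same number had correlations of -0.033, 0.059 and 0.02, and other pairs -0.077 to 0.068. Low counts limit genes near 1 TPM.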

Other observations

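The gene families given here were named by symbol and chosen after their values were seen. Of 317 tested zinc finger genes of the ZNF series, 219 rose and 7 fell, with 143 and 19 after median-of-ratios scaling and 100 and 23 under quantile normalization. Of 46 RNA helicase genes (DDX and DHX), 35 rose and 1 fell, with 23 and 5 after scaling and 27 and 1 under quantile normalization. The 10 cleavage and polyadenylation genes (CPSF and CSTF) had 9 that rose and 1 that fell under each of these settings. The 16 Integrator genes had 12 and 1, with 9 and 1 after scaling. Median log2 fold changes of the ZNF, helicase, cleavage and Integrator genes were 0.62, 0.62, 0.79 and 0.67. Genes matched on level, GC content and transcript length had 0.45, 0.27, 0.29 and 0.36, so much of the ZNF rise is shared by similar genes. Collagen genes went the other way. Of 18 tested, 11 fell and 0 rose, with 14 falling after scaling and 15 under quantile normalization. Their median log2 fold change was -0.51, where genes matched on level, GC content and transcript length had 0.24.

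The mitochondrial genome held changes in both directions, also chosen after the values were seen. MT-CYB rose from 1375 ± 218 to 2687 ± 398 TPM (SD, n = 3 each), a log2 fold change of 0.97 (SE 0.14, limma adjusted p = 0.00134). The tRNA genes MT-TL1, MT-TY and MT-TF fell by 1.49, 1.45 and 1.23 on the log2 scale (adjusted p at most 0.00118). MT-TL1 and MT-TF stood at 6342 and 2746 TPM in the controls. These genes are transcribed as long precursors, and tRNA genes lie next to MT-ND1 and MT-ND2, so shared reads leave single values uncertain.

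The tests of a weaker stimulus, of nonsense-mediated decay and of unspliced reads were chosen only after the result was seen. The labels give 10 splits of the 6 libraries into 3 and 3, too few splits for a share under 0.05. The real split gave 7515 genes past the threshold, matched by 1 of the 10 splits, itself, and the highest of the others gave 0.

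Housekeeping genes of respiration, glycolysis and the ribosome were lower than other genes, and a trend with level, GC content or transcript length is a candidate explanation. Against 10000 draws of matched genes, the oxidative phosphorylation list lay at percentile 0.01 (median -0.23 against -0.05) and the glycolysis list at percentile 0 (-0.25 against 0.10), which argues against such a trend as the whole source. Under quantile normalization both lists passed (adjusted p = 0.00065 and 4.1e-05) with smaller medians relative to all genes, -0.14 and -0.30 in place of -0.53 and -0.56, so part of the difference may go with level. The ribosomal protein list lay at percentile 0 too, but its genes stood at 1540 TPM against 187 TPM for the matched genes and quantile normalization ended the call (adjusted p = 0.39), so the draws were not a fair match and a trend with level cannot be told apart. A larger nuclear share of RNA also stays open, since 8 nuclear noncoding RNAs lay at percentile 85.57 of noncoding genes matched on level alone and went both ways. NEAT1 fell (-0.53), and MALAT1 was lower without passing (-0.47, limma adjusted p = 0.149), but passed after scaling (-0.82, adjusted p = 0.0305). PVT1, TUG1, LINC-PINT and JPX rose (1.93, 0.60, 0.475 and 0.41), of which PVT1 alone passed after scaling. An effect of PRMT1 was not tested apart from transfection.

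Immediate early genes were lower than other genes, at percentile 0 of the matched draws (median -0.75 against 0.15), which argues against a trend with level, GC content or transcript length. A weaker growth or handling stimulus at harvest may account for part of this, and 4 members rose after scaling while 20 fell. These counts had been seen before the test was set, and members answer different signals. They therefore cannot decide on the stimulus, which stays open. Neither a difference in handling between the groups nor an effect of PRMT1 itself was tested, and the labels do not say whether the controls were transfected.

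The host genes SNHG12, SNHG15 and SNHG17 rose from 2.69 to 23.1, 9.79 to 87.2 and 9.80 to 50.2 TPM, and SNHG12 and SNHG17 were chosen after their values were seen. Other host genes went both ways. GAS5, ZFAS1, SNHG1 and SNHG8 rose by 0.97, 0.77, 0.67 and 0.31 on the log2 scale, SNHG16 fell by 0.26 and SNHG5 was at -0.05. After scaling SNHG5 and SNHG16 were both lower past the threshold (limma adjusted p = 0.0176 and 0.00108). Lower nonsense-mediated decay is a candidate explanation that stays open. A list of 30 other genes with transcripts sensitive to it lay at percentile 100 of matched draws (median 0.54 against 0.14). Of them, 9 are decay factors (UPF and SMG genes), and the other 21 lay at percentile 88.84 (0.20 against 0.09). Values per gene do not separate sensitive transcripts from others of the same gene, which limits this test. Of the 30, 18 rose and 4 fell, with 13 and 9 after median-of-ratios scaling. Of the 21 without decay factors, 11 rose and 4 fell, but 7 rose and 8 fell after scaling. The 4 that fell were SNHG16, GADD45A, GADD45B and DDIT3 (-0.26, -0.70, -1.10 and -0.70). Several values of the 30 had been seen before the test. More unspliced or genomic reads would raise sense intronic genes. Of 113 tested, 14 rose and 17 fell, with 6 and 27 after scaling. They lay at percentile 0 of genes matched on level alone (median 0.14 against 0.43), which argues against more unspliced reads. Genomic reads would raise the matched genes too, so the draws cannot decide on them. An effect of PRMT1 on transcription of the host genes stays open and was not tested.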
